A study of Mus musculus with 20 samples.

How the data were processed

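Gene expression was measured by paired-end RNA sequencing in sorted CFU-E cells, the committed red cell progenitors of bone marrow, from mice of 2 genotypes. Mx1-Cre mice served as controls, and Mx1-Cre Srsf2 P95H/+ mice carried a heterozygous mutation of the splicing factor Srsf2. Mice of each genotype received saline (PBS) or phenylhydrazine (PHZ), a drug that lyses red cells and causes haemolytic anaemia, at 30 mg/kg under the skin on days 0 and 1, and CFU-E were sorted on day 4. Per the labels, each of the 4 groups held 5 libraries, and each library name carries its own animal number. P-values therefore measure the spread between these mice and libraries.

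Per the submitters' processing notes, Bowtie, RSEM 1.2.4, TopHat and TopHat2 2.0.8b and the builds hg19, GRCh37, mm10 and GRCm38 were named, with no role or order. The authors deposited 1 table of normalised expression signal with 37748 gene entries. In each library, every value divided by a single factor came out as a whole multiple of 0.01, within a tolerance of 0.01 of a step (100% of values), so the values have the form of TPM rounded to 2 decimals and multiplied by 1 factor per library. The factors ranged from 0.940 to 1.10 and the sums of the divided values from 979638 to 992743. How the authors obtained the factors is not given in the sources used here. The factors lay within 1.63% of those that a TMM scaling of the divided values gave. The deposited signal holds no read counts, so the depth behind each value is unknown, and no interval or floor that needs depth is given. The table leaves open which annotation release was used. Exact zeros are described as listed at 0.

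Values were analysed as log2(value + 1), and fold changes are differences on this scale, which understates the change of low genes. Genes with a value of at least 1 in at least 5 of the 20 libraries were kept (10890 entries). Another 17489 entries were listed at 0 in every library. Symbols were taken from the table where it names genes (4 entries) and from GENCODE vM21 for GRCm38 otherwise, which gave a symbol to 35982 entries and none to 1766. Positions are 1-based GRCm38 coordinates from that annotation. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 20 libraries, with intensity-trended and robust moderation. The 5 contrasts were PHZ against PBS in each genotype, P95H against Mx1-Cre under each treatment, and the difference between the PHZ effects of the genotypes (interaction). Tests were two-sided with Benjamini-Hochberg adjustment over the genes kept, at a threshold of 0.05.

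In all, 32 gene lists with 1074 symbols were used, of which 1067 were found and 906 passed the filter on low values. Lists were tested with camera at a preset correlation between genes of 0.01, again with the correlation estimated from the data, and adjusted over the 32 lists of a contrast. A list is said to have risen or fallen only where its camera test passed. No list passed with an estimated correlation. Mean list scores per library were compared with exact two-sided permutation tests over the 252 splits of 10 libraries. The genes named below follow a fixed rule. It takes Srsf2 and 5 genes reported as its splicing targets. It adds, among called genes with a mean of at least 5, the 6 with the largest positive and the 6 with the largest negative log2 fold change, leaving out predicted genes, pseudogenes and receptor segments. It adds up to 4 members of each list that passed or held at least 3 calls, and up to 3 members of other lists described. Where fewer than 6 genes passed, the 5 with the smallest p are named.

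The design, the lists, the naming rule and the alternatives were fixed before the data were examined, except where an alternative is said to be chosen later. The alternatives fixed beforehand were TMM factors, quantile normalization, pseudocounts of 0.1 and 5, no filter and a filter at 5, a fit of the compared groups alone, unmoderated trend, library weights, the replicate number as a block, Xist as a covariate, and leaving out each library. The alternatives added after the data were seen were the authors' factor divided out, the mean of the granulocyte and monocyte markers as a covariate, and leaving out P95H PBS replicates 4 and 5, whose marker levels were highest. The fits were tested on simulated data with 10890 genes, of which 200 were changed. For PHZ in Mx1-Cre 80% of changes of 0.5 on the log2 scale and 94% of changes of 1 were recovered, for PHZ in P95H 75% and 99%, for P95H under PBS 82% and 98%, for P95H under PHZ 82% and 97%, and for the interaction 59% and 90%. Splicing was not analysed here, since the values are per gene. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.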

Results

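The data compare CFU-E from Mx1-Cre control mice and Mx1-Cre Srsf2 P95H/+ mice (called P95H), 5 libraries per group, after PBS or after PHZ, which forces the marrow to replace lost red cells. CFU-E were sorted as live, lineage-negative, c-Kit-high cells that carried CD105 and lacked Sca-1, CD41, CD16/32 and CD150. The values are TPM-like, and their sums per library ran from 924763 to 1085047. Between 10364 and 10755 entries had a value of at least 1 in a library, and the 10 most abundant entries held 6.44% to 9.87% of the total. The sequencing depth of each library is unknown. The first principal component of the log2 values held 44.2% of the variance, with all 10 PBS libraries between -26.5 and -13.6 and all 10 PHZ libraries between 9.66 and 23.1. The second held 10.2%. Below, camera values are those with its preset correlation. With an estimated correlation no list passed in any contrast (lowest adjusted p = 0.164, megakaryocyte markers after PHZ in Mx1-Cre). By exact permutation tests of mean scores, no list passed after adjustment in P95H against Mx1-Cre. The lowest adjusted p of these tests was 0.17 under PBS and 0.127 under PHZ.

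Srsf2, the gene that carries the mutation and encodes a serine and arginine-rich splicing factor, was expressed in every library. Its mean was 679 ± 31.9 (SD, n = 5) in Mx1-Cre PBS, 685 ± 35.6 in Mx1-Cre PHZ, 623 ± 49.3 in P95H PBS and 586 ± 20.2 in P95H PHZ. Expression per gene does not show the P95H change itself, so these values do not check the genotype. Srsf2 was lower in P95H than in Mx1-Cre after PHZ (log2 fold change -0.22, SE 0.0547, adjusted p = 0.0188), with 5 of 5 P95H libraries below every control. It lost that call without Mx1-Cre PHZ replicate 5 (adjusted p = 0.0515), under quantile normalization and with the authors' factor divided out (adjusted p up to 0.0986). Under PBS the difference missed the threshold (log2 fold change -0.13, SE 0.0547, adjusted p = 0.288). Fyn, the Src family kinase named in the study's title, averaged 6.48 ± 0.761 in Mx1-Cre PBS, 6.69 ± 0.81 in Mx1-Cre PHZ, 6.68 ± 0.997 in P95H PBS and 6.59 ± 0.548 in P95H PHZ. No contrast called it, and the P95H effect was 0.03 (SE 0.0953, adjusted p = 0.913) under PBS and -0.01 (SE 0.0953, adjusted p = 0.949) under PHZ. Ezh2, Ints3, Casp8 and Bcor, reported elsewhere as SRSF2 splicing targets, were called in none of the 5 contrasts. Their nearest approach to the threshold was Ints3 after PHZ in Mx1-Cre (log2 fold change 0.17, SE 0.0692, adjusted p = 0.0634). Srsf2 is ENSMUSG00000034120, chromosome 11, 116849901 to 116853094, minus strand, and Fyn is ENSMUSG00000019843, chromosome 10, 39368855 to 39565381, plus strand.

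**Figure D1:**
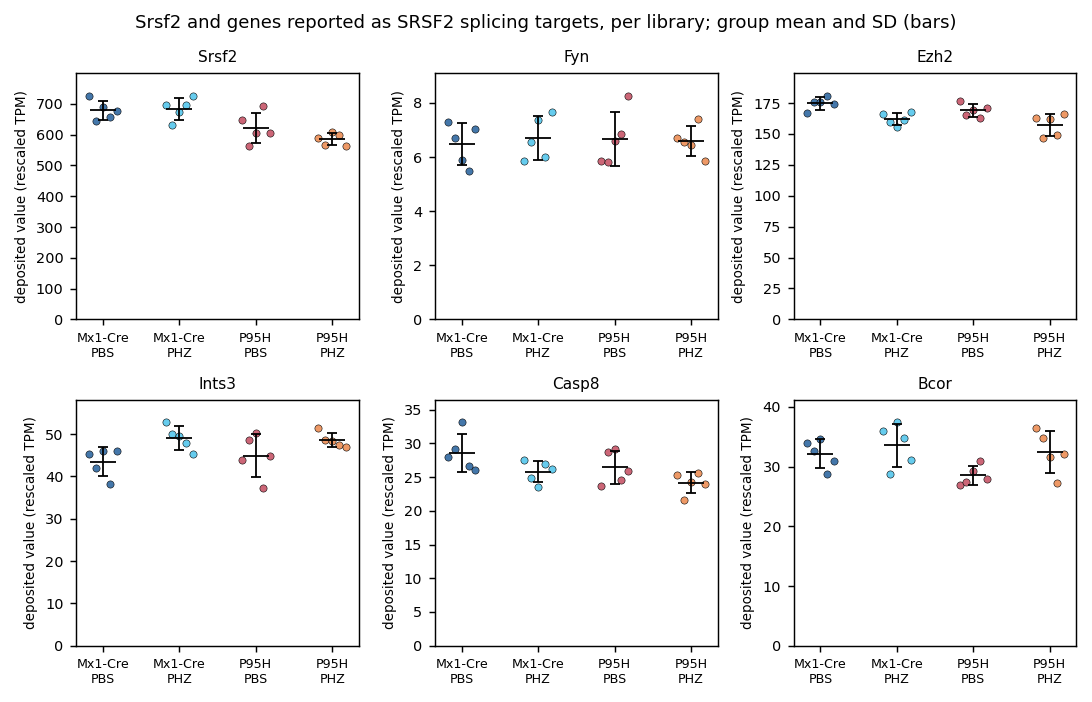
Deposited values (TPM-like, vertical axis from 0) of Srsf2, Fyn, Ezh2, Ints3, Casp8 and Bcor in the 4 groups. Points are libraries, and bars show the group mean and SD of 5. Srsf2 averages 586 in P95H PHZ against 685 in Mx1-Cre PHZ, while Fyn averages between 6.48 and 6.69 in every group.

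In Mx1-Cre mice, the comparison of PHZ with PBS asks how normal CFU-E respond to haemolytic anaemia. Podxl, a sialomucin of the CD34 family, rose from 1.82 ± 1.02 to 200 ± 29.4 (log2 fold change 6.25, SE 0.36, n = 5 per group), and Fabp5, a fatty acid carrier, from 48.8 ± 10.7 to 652 ± 70.8 (log2 fold change 3.74, SE 0.134). The EPO and STAT5 targets Erfe, the hormone that lowers hepcidin, Socs2, a feedback inhibitor of cytokine signalling, and Ccnd2, a D-type cyclin, rose by 3.12 (SE 0.31), 1.61 (SE 0.13) and 1.48 (SE 0.164). Genes of cholesterol synthesis, ribosome biogenesis, glycolysis, the amino acid response and the mTORC1-responsive list rose, while interferon-stimulated genes and cytosolic ribosomal protein genes fell. In limma, 1856 genes were higher and 1618 lower of 10890 tested, 91 and 80 of them by more than 1 on the log2 scale. With the authors' factor divided out, an alternative chosen after the data were seen, the split was 2237 higher and 1215 lower. Without overlap between the groups were 2444 genes (22.4%), where chance gives 0.794%.

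The other leading increases of this comparison were C2cd4a (log2 fold change 4.77, SE 0.222), Cda, which deaminates cytidine (log2 fold change 4.08, SE 0.198), Plek2, an actin regulator of erythroid cells (log2 fold change 3.78, SE 0.202), and Fam124a (log2 fold change 3.55, SE 0.151). The leading decreases were the adhesion protein gene Amigo2 (log2 fold change -2.45, SE 0.244), Tceal3 (log2 fold change -2.13, SE 0.208), the phosphatase gene Ptpn13 (log2 fold change -1.90, SE 0.14) and Spon2, which encodes an extracellular matrix protein (log2 fold change -1.78, SE 0.133). H2-Q7 (log2 fold change -2.72, SE 0.388) and H2-Q6 (log2 fold change -2.37, SE 0.4), class Ib histocompatibility genes, are near-identical copies between which reads can be split, so their single values are uncertain. In each of these genes 5 of 5 PHZ libraries lay beyond every PBS library, and adjusted p was at most 0.00031 (limma).

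Of 183 measured mTORC1-responsive genes, listed as responding to the growth-promoting mTORC1 kinase, 113 were higher, 5 lower and 65 not called (115 higher and 9 lower adjusted over the list alone, median log2 fold change 0.24, camera adjusted p = 1.14e-15). They include Ctsc, a lysosomal protease (2.02, SE 0.161), Slc9a3r1, a membrane scaffold (1.17, SE 0.0838), and Mthfd2 and Shmt2 of mitochondrial folate metabolism (1.42, SE 0.127, and 0.77, SE 0.0733). Among 34 genes of the pathway itself 10 were higher and 7 lower (10 and 8 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.298). Castor1, an arginine sensor that restrains mTORC1, rose by 1.33 (SE 0.119) and Akt1, a kinase upstream of it, by 0.39 (SE 0.0641).

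Of 24 cholesterol synthesis genes, 21 were higher, 0 lower and 3 not called (21 higher and 0 lower adjusted over the list alone, median 0.71, camera adjusted p = 5.39e-12). Idi1, an isoprenoid isomerase, rose by 0.93 (SE 0.102), and Stard4, a sterol carrier, by 1.42 (SE 0.162). Of 40 ribosome biogenesis genes, 30 were higher, 0 lower and 10 not called (32 higher and 0 lower adjusted over the list alone, median 0.29, camera adjusted p = 1.86e-10). Members include Heatr1 (0.60, SE 0.0828) and Polr1a, the large subunit of RNA polymerase I (0.40, SE 0.0625). Of 23 glycolysis genes, 15 were higher, 2 lower and 6 not called (15 higher and 2 lower adjusted over the list alone, median 0.28, camera adjusted p = 4.37e-05). Members include Hk1 (0.43, SE 0.0526) and Pfkp (0.88, SE 0.118) of the early steps. Of 25 genes of the ATF4 and amino acid response, 16 were higher, 2 lower and 7 not called (17 higher and 3 lower adjusted over the list alone, median 0.33, camera adjusted p = 2.03e-06). Members include Psat1 of serine synthesis (0.80, SE 0.0895) and the stress protein gene Nupr1 (1.58, SE 0.18). Of 22 genes of the unfolded protein response, 15 were higher, 0 lower and 7 not called (16 higher and 1 lower adjusted over the list alone, median 0.31, camera adjusted p = 4.37e-05). Members include Edem1 (0.42, SE 0.0584) and the chaperone gene Calr (0.47, SE 0.091). With the granulocyte covariate 7 were higher and 0 lower.

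Of 19 EPO and STAT5 response genes, 10 were higher, 2 lower and 7 not called (10 higher and 6 lower adjusted over the list alone, median 0.36, camera adjusted p = 0.024). That list lost its call without Mx1-Cre PHZ replicate 1 (adjusted p = 0.0504), and its median was 0.21 without Mx1-Cre PHZ replicate 4. It also missed the threshold under the filter at 5 (adjusted p = 0.182) and in a fit of the compared groups alone (adjusted p = 0.057). Of 22 interferon-stimulated genes, 0 were higher, 17 lower and 5 not called (0 higher and 18 lower adjusted over the list alone, median -0.72, camera adjusted p = 2.39e-09). Members include Irf7, a regulator of the interferon response (-1.25, SE 0.195), Trim30a (-1.14, SE 0.137) and Rtp4 (-1.71, SE 0.26). Of 77 cytosolic ribosomal protein genes, many of which have processed copies that make single values uncertain, 6 were higher, 45 lower and 26 not called (6 higher and 53 lower adjusted over the list alone, median -0.23, camera adjusted p = 2.83e-08). Rpl17 and Rps7 fell by 0.40 (SE 0.0884) and 0.31 (SE 0.069), and under quantile normalization 7 members were higher, 19 lower and the median was -0.06. With the granulocyte covariate 3 were higher and 12 lower. Of 73 oxidative phosphorylation genes, 2 were higher, 14 lower and 57 not called (0 higher and 12 lower adjusted over the list alone, median -0.07, camera adjusted p = 0.00419). Members include Atp5e (-0.36, SE 0.0667) and Uqcrh (-0.33, SE 0.0674). That median was -0.11 without Mx1-Cre PHZ replicate 5, -0.11 under quantile normalization (0 higher, 28 lower) and -0.02 with the authors' factor divided out. The granulocyte covariate gave 0 higher and 7 lower and ended the call (adjusted p = 0.0658). The adjusted exact permutation p was 0.145, and 0.0597 for ribosomal proteins.

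Tfrc, the transferrin receptor that brings iron into the cell, rose from 366 ± 37.7 to 682 ± 73 (log2 fold change 0.90, SE 0.116). Among 12 stem and early progenitor genes, Myb and Gata2, transcription factors of immature cells, fell by 0.67 (SE 0.0975) and 0.85 (SE 0.153), while Cd48, a surface receptor of progenitors, rose by 1.63 (SE 0.221); the list held 1 higher and 5 lower (1 and 6 adjusted over the list alone) and did not pass (camera adjusted p = 0.0626). Of 35 erythroid maturation genes, 7 were higher, 8 lower and 20 not called (8 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.215). The blood group genes Rhag and Rhd went apart (log2 fold change 0.29, SE 0.0583, and -0.44, SE 0.0798). Of 6 megakaryocyte markers, 0 were higher, 4 lower and 2 not called (0 higher and 5 lower adjusted over the list alone, median -0.48, camera adjusted p = 0.00455). Members include Gp9 at -0.92 (SE 0.149) and Itga2b, which encodes CD41, at -0.55 (SE 0.116). Of the 11 Src family kinases and regulators, Pag1, a membrane adaptor of the inhibitory kinase Csk, rose by 0.82 (SE 0.101) and Lyn by 0.27 (SE 0.0759), and the list held 2 higher and 2 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.853).

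Markers of granulocytes and monocytes, cells the sort should exclude, averaged lower after PHZ. Their mean log2 value was 3.52 ± 0.39 (SD, n = 5) in Mx1-Cre PBS and 2.67 ± 0.82 after PHZ. The exact permutation p was 0.0635 (0.107 after adjustment). The neutrophil gene S100a9 averaged 215 ± 80.7 and 145 ± 138. Of 18 markers, 0 were higher, 1 lower and 17 not called (0 higher and 0 lower adjusted over the list alone, median -0.83, camera adjusted p = 0.00324). The single call, Ms4a3, was lost without any 1 of Mx1-Cre PBS replicate 4 or PHZ replicates 1, 2 and 3 (adjusted p = 0.0609 to 0.0863). Of 3 lymphoid markers, 0 were higher, 1 lower and 2 not called (0 higher and 3 lower adjusted over the list alone, median -0.71, camera adjusted p = 0.161). Their mean scores fell from 1.07 to 0.31 (exact permutation p = 0.00794, 0.0181 after adjustment). Of the 12 basophil and mast cell markers 1, Il4, passed the filter, and it rose (log2 fold change 0.60, SE 0.194, adjusted p = 0.0221), a call lost with the granulocyte covariate (adjusted p = 0.147) and without Mx1-Cre PBS replicate 5 or Mx1-Cre PHZ replicate 4 (adjusted p = 0.0689 and 0.0653). The 1 macrophage marker measured, Cd68, was not called (-0.06). Il4 and Cd68 were named after their values were seen. The interferon-stimulated, ribosomal protein and oxidative phosphorylation lists fell between the same groups. With the marker mean as a covariate, chosen later, 1339 genes were higher and 1104 lower.

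In P95H mice, the same treatment was compared to ask how CFU-E with mutant Srsf2 respond. Podxl rose from 3.82 ± 2.76 to 204 ± 37.4 (log2 fold change 5.61, SE 0.36, n = 5 per group), Fabp5 from 54.7 ± 8.25 to 670 ± 55.6 (log2 fold change 3.60, SE 0.134) and Erfe from 2.33 ± 1.32 to 21.3 ± 7.67 (log2 fold change 2.76, SE 0.31). Cholesterol synthesis, mTORC1-responsive, amino acid response and glycolysis genes rose, and interferon-stimulated, ribosomal protein and oxidative phosphorylation genes fell. limma called 1371 genes higher and 1923 lower, 97 and 115 of them by more than 1 on the log2 scale, and 1918 genes (17.6%) had no overlap between the groups, where chance gives 0.794%. With the authors' factor divided out the split was 2585 higher and 1112 lower.

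The leading increases also held C2cd4a (log2 fold change 4.52, SE 0.222), Plek2 (log2 fold change 3.79, SE 0.202), Cda (log2 fold change 3.56, SE 0.198) and Cpd, which encodes a carboxypeptidase (log2 fold change 3.48, SE 0.198). The leading decreases held Amigo2 (log2 fold change -2.49, SE 0.244), Khdrbs3, an RNA-binding protein gene (log2 fold change -2.43, SE 0.222), Rtp4 (log2 fold change -2.60, SE 0.26), Elane, the neutrophil elastase gene (log2 fold change -2.44, SE 0.593), and the near-identical copies H2-Q6 (log2 fold change -3.31, SE 0.4) and H2-Q7 (log2 fold change -3.15, SE 0.388), whose single values are uncertain. In all of these, 5 of 5 PHZ libraries lay beyond every PBS library, and adjusted p was at most 0.00501 (limma). Elane lost its call without P95H PBS replicates 4 and 5 (adjusted p = 0.0639).

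Of 183 mTORC1-responsive genes, 74 were higher, 12 lower and 97 not called (80 higher and 13 lower adjusted over the list alone, median 0.16, camera adjusted p = 1.05e-08). Members include Ctsc (2.05, SE 0.161), Slc9a3r1 (0.90, SE 0.0838) and Mthfd2 (1.29, SE 0.127). With the authors' factor divided out 113 were higher and 8 lower with a median of 0.26, and with the granulocyte covariate 27 were higher and 1 lower. Of 34 mTORC1 pathway components, 5 were higher, 5 lower and 24 not called (7 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.388). Eif4ebp1, a translational repressor that mTORC1 inactivates, fell by 0.46 (SE 0.0794) and Sesn2, a leucine sensor that restrains it, by 0.42 (SE 0.0881). Of 24 cholesterol synthesis genes, 19 were higher, 0 lower and 5 not called (22 higher and 0 lower adjusted over the list alone, median 0.55, camera adjusted p = 8.73e-09). Members include Cyp51 (0.95, SE 0.169) and Idi1 (0.74, SE 0.102), and with the granulocyte covariate 8 were higher and 0 lower. Of 25 genes of the ATF4 and amino acid response, 12 were higher, 3 lower and 10 not called (12 higher and 3 lower adjusted over the list alone, median 0.23, camera adjusted p = 0.00044). Members include Nupr1 at 1.46 (SE 0.18). Of 23 glycolysis genes, 11 were higher, 2 lower and 10 not called (13 higher and 2 lower adjusted over the list alone, median 0.16, camera adjusted p = 0.00303). Members include Pfkp at 0.96 (SE 0.118), and the median was 0.27 with the authors' factor divided out and 0.25 with the granulocyte covariate.

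Of 40 ribosome biogenesis genes, 11 were higher, 0 lower and 29 not called (11 higher and 0 lower adjusted over the list alone, median 0.11, camera adjusted p = 0.00128). Members include Heatr1 at 0.39 (SE 0.0828), and the median was 0.07 without P95H PHZ replicate 2 and 0.20 without P95H PHZ replicate 5. Under quantile normalization 16 of these were higher and 0 lower. With the authors' factor divided out 22 were higher and 0 lower with a median of 0.22, and with the granulocyte covariate 1 was higher. The exact permutation p of its mean scores was 0.183 (0.264 after adjustment). Of 19 EPO and STAT5 response genes, 9 were higher, 4 lower and 6 not called (9 higher and 4 lower adjusted over the list alone, median 0.19, camera adjusted p = 0.00311). Members include Socs2 at 1.57 (SE 0.13) and Ccnd2 at 1.35 (SE 0.164). That median was 0.13 without P95H PBS replicate 3, 0.12 without P95H PBS replicate 5, 0.02 without P95H PHZ replicate 2, 0.08 without P95H PHZ replicate 4 and 0.30 without P95H PHZ replicate 5. It turned to -0.02 with the granulocyte covariate, which also ended the call of Heatr1 (adjusted p = 0.181). Under the filter at 5 the EPO and STAT5 median was 0.03 and the list missed the threshold (adjusted p = 0.0697), and with the authors' factor divided out 9 members were higher and 0 lower. Of 22 genes of the unfolded protein response, 5 were higher, 1 lower and 16 not called (5 higher and 1 lower adjusted over the list alone, median 0.19, camera adjusted p = 0.0145). The call was lost without P95H PBS replicate 4 or P95H PHZ replicate 4 (adjusted p = 0.0652 and 0.0671). The exact permutation p was 0.119. With the authors' factor divided out 15 were higher and 1 lower (median 0.30), and with the granulocyte covariate 1 and 1. Of 30 mitosis genes, 10 were higher, 1 lower and 19 not called (12 higher and 1 lower adjusted over the list alone, median 0.11, camera adjusted p = 0.0216). Members include the spindle genes Kif23 (0.62, SE 0.101) and Hmmr (0.46, SE 0.092). The list lost its call without P95H PHZ replicate 1 or 5 (adjusted p = 0.0754 and 0.114). Its median was 0.21 with the authors' factor divided out, and its exact permutation p was 0.0794 (0.169 after adjustment). The granulocyte covariate ended the calls of both lists (adjusted p = 0.884 and 0.226) and of Kif23 and Hmmr (0.0682 and 0.319). Without P95H PBS replicates 4 and 5 both lists lost theirs (adjusted p = 0.106 and 0.062).

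Of 22 interferon-stimulated genes, 0 were higher, 20 lower and 2 not called (1 higher and 20 lower adjusted over the list alone, median -1.16, camera adjusted p = 6.46e-12). Members include Trim30a (-1.37, SE 0.137) and Xaf1 (-1.85, SE 0.225). Of 77 cytosolic ribosomal protein genes, 1 was higher, 64 lower and 12 not called (2 higher and 65 lower adjusted over the list alone, median -0.34, camera adjusted p = 7.46e-15). Members include Rps4x (-0.45, SE 0.0718) and Rps7 (-0.42, SE 0.069). Under quantile normalization 3 of these were higher, 26 lower and the median was -0.10. It was -0.21 with the granulocyte covariate. Of 73 oxidative phosphorylation genes, 0 were higher, 45 lower and 28 not called (0 higher and 53 lower adjusted over the list alone, median -0.22, camera adjusted p = 2.43e-11). Members include Ndufs4 of complex I (-0.41, SE 0.0554) and Atp5e (-0.46, SE 0.0667). When the authors' factor was divided out 0 of these were higher, 25 lower and the median was -0.12. Tfrc rose by 0.75 (SE 0.116), Pag1 by 0.93 (SE 0.101), and Myb fell by 0.74 (SE 0.0975). The megakaryocyte marker Gp9 fell by 0.57 (SE 0.149) in a list of 6 with 3 lower (5 adjusted over the list alone) that did not pass (camera adjusted p = 0.0519).

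Granulocyte and lymphoid markers fell with the treatment in P95H mice. Of 18 granulocyte and monocyte markers, 0 were higher, 18 lower and 0 not called (0 higher and 18 lower adjusted over the list alone, median -1.84, camera adjusted p = 2.41e-07). Members include Mpo at -2.34 (SE 0.556) and Retnlg at -1.55 (SE 0.335). Their mean log2 value was 4.39 ± 0.80 (SD, n = 5) in P95H PBS and 2.72 ± 0.49 in P95H PHZ, and S100a9 averaged 472 ± 268 and 116 ± 56.9. Of 3 lymphoid markers, 0 were higher, 3 lower and 0 not called (0 higher and 3 lower adjusted over the list alone, median -1.43, camera adjusted p = 0.0186). Members include the B cell gene Cd79a at -1.25 (SE 0.232). Il4, the 1 basophil and mast cell marker measured, rose (1.06, SE 0.194, adjusted p = 0.000289), a call lost with the covariate (adjusted p = 0.0895), and the macrophage marker Cd68 was not called (0.01). The lists named above as higher or lower moved between the same groups. With the granulocyte covariate 439 genes were higher and 553 lower, and without P95H PBS replicates 4 and 5, 837 and 1252, both chosen later. The covariate differed between the groups and raised SEs (Cd68 0.125 to 0.175, Il4 0.194 to 0.257), so this alone can end calls. With the covariate the ribosomal protein calls were 0 higher and 7 lower, and those of oxidative phosphorylation 0 and 9. It also ended the calls of Gp9 (adjusted p = 0.115) and Eif4ebp1 (adjusted p = 0.0596), and leaving out P95H PBS replicates 4 and 5 that of Mpo (adjusted p = 0.0573).

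The comparison of P95H with Mx1-Cre under PBS asks what the mutation does in undisturbed marrow. Interferon-stimulated genes were higher in P95H: Rtp4 rose from 3.89 ± 1.19 to 12.1 ± 6.5 (log2 fold change 1.33, SE 0.26, n = 5 per group) and Ifitm3, an antiviral membrane protein gene, from 62.4 ± 19.5 to 123 ± 37.4 (log2 fold change 0.98, SE 0.19). Smo, the signal transducer of the Hedgehog pathway, fell from 18 ± 1.78 to 10.2 ± 1.71 (log2 fold change -0.77, SE 0.102), and Rbks, which encodes ribokinase, from 25.6 ± 1.33 to 15 ± 1.16 (log2 fold change -0.73, SE 0.0909). Zmat3, an RNA-binding p53 target, rose by 0.71 (SE 0.134). limma called 39 genes higher and 122 lower of 10890, 4 and 1 of them by more than 1 on the log2 scale, and 400 genes (3.67%) had no overlap between the groups, where chance gives 0.794%. Under quantile normalization the split was 52 higher and 80 lower. The count of 161 was 538 with library weights and 78 in a fit of the compared groups alone.

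The other leading genes were Tnfsf13os (log2 fold change 1.07, SE 0.171), which lies antisense to another gene and is uncertain because strand use is not given in the sources used here, Tmem86b (log2 fold change 0.62, SE 0.124), Tspan15, a tetraspanin gene (log2 fold change -0.78, SE 0.126), and Slc25a23, a mitochondrial carrier gene (log2 fold change -0.72, SE 0.0948). In these, and in Rtp4, Ifitm3, Zmat3, Smo and Rbks, 5 of 5 P95H libraries lay beyond every Mx1-Cre library (adjusted p at most 0.0109, limma). Rtp4 lost its call with the granulocyte covariate, under a pseudocount of 0.1 and in a fit of the compared groups alone (adjusted p up to 0.0948). The last of these also ended the calls of Ifitm3 (adjusted p = 0.142), Tmem86b (adjusted p = 0.0598) and Armcx2 (adjusted p = 0.0963), and Tmem86b lost its call without P95H PBS replicates 4 and 5 (adjusted p = 0.0746). Oas1a, an antiviral enzyme gene (log2 fold change 1.15, SE 0.257, adjusted p = 0.0294), lost its call without any 1 of Mx1-Cre PBS replicates 2, 4 and 5 or P95H PBS replicates 3, 4 and 5 (adjusted p = 0.0532 to 0.0701). Armcx2 (log2 fold change -0.66, SE 0.155, adjusted p = 0.0347) lost it without any 1 of Mx1-Cre PBS replicates 1 and 4 or P95H PBS replicates 1, 3, 4 and 5 (adjusted p = 0.0617 to 0.0875), and Marcksl1 (log2 fold change -0.65, SE 0.15, adjusted p = 0.0299) without any 1 of Mx1-Cre PBS replicates 2, 3, 4 and 5 or P95H PBS replicates 2, 3 and 5 (adjusted p = 0.0501 to 0.084) and under quantile normalization (adjusted p = 0.0673). Oas1a and Armcx2 also lost their calls with the granulocyte covariate (adjusted p = 0.078 and 0.116) and without P95H PBS replicates 4 and 5 (adjusted p = 0.133 and 0.165). A pseudocount of 0.1 ended both calls (adjusted p = 0.06 and 0.0529), and fitting with no filter those of Armcx2 and Marcksl1 (adjusted p up to 0.0746).

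Of 22 interferon-stimulated genes, 2 were higher, 0 lower and 20 not called (14 higher and 0 lower adjusted over the list alone, median 0.46, camera adjusted p = 2.15e-14). The mean score of this list was 3.60 ± 0.36 (SD, n = 5) in P95H PBS and 3.09 ± 0.19 in Mx1-Cre PBS. The exact permutation p was 0.0159 (0.17 after adjustment). Bst2, a member that missed the threshold, had a log2 fold change of 0.55 (SE 0.142, adjusted p = 0.0627). Of 22 p53 targets, 3 were higher, 1 lower and 18 not called (5 higher and 2 lower adjusted over the list alone, median 0.03, camera adjusted p = 0.021). Besides Zmat3, Phlda3, an inhibitor of Akt (0.66, SE 0.142), and Dglucy (0.56, SE 0.131) were higher, and Ddb2, a DNA damage sensor, was lower (-0.38, SE 0.0951). Phlda3 lost its call without any 1 of Mx1-Cre PBS replicate 4 or P95H PBS replicate 5 (adjusted p = 0.0551 to 0.0592), Dglucy without any 1 of Mx1-Cre PBS replicates 2, 3, 4 and 5 or P95H PBS replicates 3, 4 and 5 (adjusted p = 0.0515 to 0.107), and Ddb2 without any 1 of Mx1-Cre PBS replicates 1, 3, 4 and 5 or P95H PBS replicates 1, 3, 4 and 5 (adjusted p = 0.0572 to 0.131). Dglucy and Ddb2 also lost theirs with the granulocyte covariate (adjusted p = 0.112 and 0.124) and without P95H PBS replicates 4 and 5 (adjusted p = 0.228 and 0.174). Ddb2 further lost its call under TMM factors and quantile normalization (adjusted p = 0.0542 and 0.103), and a fit of the compared groups alone ended the calls of Phlda3, Dglucy and Ddb2 (adjusted p up to 0.0963). With no filter Dglucy, Ddb2 and the p53 list (adjusted p = 0.0655) missed the threshold. The list lost its call without any 1 of Mx1-Cre PBS replicate 5 or P95H PBS replicate 5 (adjusted p = 0.06 to 0.0738), and its median was 0.06 without Mx1-Cre PBS replicate 2, 0.07 without Mx1-Cre PBS replicate 4 and 0.05 without P95H PBS replicate 4. It was 0.06 under quantile normalization and 0.01 with the granulocyte covariate, and the p53 list missed the threshold under the filter at 5 (adjusted p = 0.385).

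The mTORC1-responsive list passed with a median of 0.03 and no member called (camera adjusted p = 0.00144), with 0 higher and 0 lower adjusted over the list alone. Without Mx1-Cre PBS replicate 4 its median was -0.01 (adjusted p = 0.567), without Mx1-Cre PBS replicate 5 it was 0.05, and without P95H PBS replicate 1 it was 0.01. Pfkl and Cdkn1a, its members nearest the threshold, had log2 fold changes of -0.20 (SE 0.0582, adjusted p = 0.0912) and 0.78 (SE 0.233, adjusted p = 0.108). Oxidative phosphorylation (median 0.04, camera adjusted p = 0.0033), ribosome biogenesis (median 0.04, camera adjusted p = 0.0118), cytosolic ribosomal proteins (median 0.02, camera adjusted p = 0.00907) and the amino acid response (median 0.06, camera adjusted p = 0.021) also passed with 0 members higher and 0 lower, adjusted over all genes or adjusted over the list alone. The call of oxidative phosphorylation was lost without any 1 of Mx1-Cre PBS replicate 1 or P95H PBS replicate 1 (adjusted p = 0.0525 to 0.291), that of ribosome biogenesis without any 1 of Mx1-Cre PBS replicate 4 or P95H PBS replicate 1 (adjusted p = 0.178 to 0.301), that of ribosomal proteins without any 1 of Mx1-Cre PBS replicates 1 and 2 or P95H PBS replicates 1 and 4 (adjusted p = 0.0548 to 0.394) and that of the amino acid response without any 1 of Mx1-Cre PBS replicate 4 or P95H PBS replicates 1 and 3 (adjusted p = 0.0603 to 0.627). The ribosome biogenesis median was 0.07 without Mx1-Cre PBS replicate 5, 0.08 without P95H PBS replicate 2 and 0.02 without P95H PBS replicate 3. The ribosomal protein median was 0.07 without Mx1-Cre PBS replicate 4, 0.06 without P95H PBS replicate 2 and 0.05 without P95H PBS replicate 3, and it turned below 0 without Mx1-Cre PBS replicate 2 or P95H PBS replicate 4. The amino acid median turned below 0 without Mx1-Cre PBS replicate 4. Quantile normalization ended all 4 calls (adjusted p = 0.41, 0.0933, 0.421 and 0.0603), and so did fitting with no filter (adjusted p = 0.0655, 0.115, 0.133 and 0.0655). The granulocyte covariate ended those of oxidative phosphorylation and ribosomal proteins (adjusted p = 0.371 and 0.975), library weights that of the amino acid response (0.18) and an Xist covariate that of ribosomal proteins (0.101). Il1r1, the interleukin 1 receptor, fell by 0.57 (SE 0.0989, adjusted p = 0.00373), and Car1, a carbonic anhydrase gene of erythroid cells, missed the threshold (log2 fold change -0.47, SE 0.121, adjusted p = 0.0587).

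Granulocyte and monocyte markers were higher in P95H PBS, with a mean log2 value of 4.39 ± 0.80 against 3.52 ± 0.39 (SD, n = 5; exact permutation p = 0.0794, 0.399 after adjustment). Of 18 markers, 0 were higher, 0 lower and 18 not called (0 higher and 0 lower adjusted over the list alone, median 0.89, camera adjusted p = 1.09e-10). The median was 0.42 without P95H PBS replicates 4 and 5. Fcnb and Retnlg had log2 fold changes of 1.31 (SE 0.384, adjusted p = 0.107) and 0.98 (SE 0.335, adjusted p = 0.171). Of 3 lymphoid markers, 0 were higher, 0 lower and 3 not called (0 higher and 0 lower adjusted over the list alone, median 0.54, camera adjusted p = 0.021). Members include Nkg7 at 0.70 (SE 0.31, adjusted p = 0.318). The lymphoid call was lost without any 1 of Mx1-Cre PBS replicates 1 and 2 or P95H PBS replicate 3 (adjusted p = 0.0526 to 0.123), and its median was 0.36 without Mx1-Cre PBS replicate 4. Quantile normalization and a fit of the compared groups alone ended it as well (adjusted p = 0.0716 and 0.0602). The interferon-stimulated list was higher in the same group. With the granulocyte covariate 20 genes were higher and 87 lower, and without P95H PBS replicates 4 and 5, 20 and 77, both chosen after the data were seen. The full count of 161 was 92 without Mx1-Cre PBS replicate 1, 93 without Mx1-Cre PBS replicate 3 and 90 without P95H PBS replicate 5.

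The comparison of P95H with Mx1-Cre after PHZ asks what the mutation does under demand for red cells. Smo averaged 18.2 ± 2.13 in Mx1-Cre and 10 ± 1.38 in P95H (log2 fold change -0.80, SE 0.102, n = 5 per group), and Rbks 23.4 ± 2.74 and 13.3 ± 2.07 (log2 fold change -0.78, SE 0.0909). Some genes of oxidative phosphorylation were called lower in P95H, led by the complex I subunit genes Ndufb8 (312 ± 23.5 to 234 ± 13.4, log2 fold change -0.41, SE 0.0652) and Ndufb2 (log2 fold change -0.34, SE 0.059). Car1 averaged 3620 ± 567 and 2390 ± 287 (log2 fold change -0.59, SE 0.121). limma called 120 genes higher and 476 lower, 1 and 3 of them by more than 1 on the log2 scale, and 757 genes (6.95%) had no overlap, where chance gives 0.794%. The surplus of lower calls depended on scaling: quantile normalization gave 129 higher and 163 lower, and the authors' factor divided out gave 133 higher and 145 lower. The count of 596 was 319 without Mx1-Cre PHZ replicate 3, 331 without P95H PHZ replicate 3 and 345 in a fit of the compared groups alone.

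Other leading decreases were Spon2 (log2 fold change -0.86, SE 0.133), Ephx2, which encodes an epoxide hydrolase (log2 fold change -0.84, SE 0.145), and Spata5l1 (log2 fold change -0.71, SE 0.128). Leading increases were Cd59b, a complement inhibitor gene (log2 fold change 0.62, SE 0.0994), the noncoding transcript Eldr (log2 fold change 0.61, SE 0.124), Dqx1 (log2 fold change 0.58, SE 0.121) and Dpp7, which encodes a dipeptidyl peptidase (log2 fold change 0.53, SE 0.102). In these, and in Smo, Rbks, Ndufb8, Ndufb2 and Car1, 5 of 5 P95H libraries lay beyond every Mx1-Cre library (adjusted p at most 0.00709, limma). Prss50 (log2 fold change -0.71, SE 0.175, adjusted p = 0.0231) lost its call without any 1 of Mx1-Cre PHZ replicates 3 and 5 or P95H PHZ replicates 2, 3 and 5 (adjusted p = 0.0509 to 0.0686). App, the amyloid precursor protein gene (log2 fold change 0.83, SE 0.238, adjusted p = 0.0473), lost it without any 1 of Mx1-Cre PHZ replicates 3, 4 and 5 or P95H PHZ replicates 1, 2, 3 and 4 (adjusted p = 0.0558 to 0.118), and Phldb1 (log2 fold change 0.53, SE 0.157, adjusted p = 0.0491) without any 1 of Mx1-Cre PHZ replicates 1, 2, 3 and 5 or P95H PHZ replicates 3, 4 and 5 (adjusted p = 0.0709 to 0.133). Quantile normalization ended the calls of Prss50 and Phldb1 (adjusted p = 0.0684 and 0.0533), and the authors' factor divided out those of App and Phldb1 (adjusted p = 0.06 and 0.0579). App and Phldb1 were also lost in a fit of the compared groups alone (adjusted p = 0.0505 and 0.136), with no filter (adjusted p = 0.0552 and 0.0688) and under a pseudocount of 0.1 (adjusted p = 0.0754 and 0.0575).

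Of 73 oxidative phosphorylation genes, 0 were higher, 6 lower and 67 not called (0 higher and 12 lower adjusted over the list alone, median -0.09, camera adjusted p = 0.00671). Exact permutation p was 0.0714 for this list, 0.0794 for cholesterol synthesis and 0.0952 for ribosome biogenesis, each 0.317 after adjustment. Ndufb11 (-0.24, SE 0.0659) lost its call without any 1 of Mx1-Cre PHZ replicates 1, 3 and 5 or P95H PHZ replicates 3 and 5 (adjusted p = 0.0701 to 0.0891), and Atp5j (-0.24, SE 0.0682) without any 1 of Mx1-Cre PHZ replicates 3, 4 and 5 or P95H PHZ replicates 3, 4 and 5 (adjusted p = 0.051 to 0.114). Both also lost their calls under quantile normalization and with the authors' factor divided out (adjusted p up to 0.109), and Atp5j in a fit of the compared groups alone and with no filter. The list lost its call without any 1 of Mx1-Cre PHZ replicate 5 or P95H PHZ replicates 3 and 5 (adjusted p = 0.0513 to 0.406) and under quantile normalization (median -0.02, adjusted p = 0.155). With the authors' factor divided out its median was -0.03. Of 24 cholesterol synthesis genes, 0 were higher, 1 lower and 23 not called (0 higher and 1 lower adjusted over the list alone, median -0.25, camera adjusted p = 0.0114). The call was lost without any 1 of Mx1-Cre PHZ replicate 3 or P95H PHZ replicate 1 (adjusted p = 0.101 to 0.107), and Dhcr7, the reductase of the last step (-0.44, SE 0.105), lost its own without P95H PHZ replicate 3 (adjusted p = 0.0539). Dhcr7 also missed the threshold under quantile normalization (adjusted p = 0.0728), in a fit of the compared groups alone (adjusted p = 0.0665) and with the authors' factor divided out (adjusted p = 0.0621). Of 40 ribosome biogenesis genes, 0 were higher, 0 lower and 40 not called (0 higher and 0 lower adjusted over the list alone, median -0.14, camera adjusted p = 0.0141). The call was lost without any 1 of Mx1-Cre PHZ replicates 3 and 5 or P95H PHZ replicates 3 and 5 (adjusted p = 0.0667 to 0.495) and under quantile normalization (median -0.07, adjusted p = 0.0952), and the median was -0.08 with the authors' factor divided out. Under the filter at 5 the calls of the oxidative phosphorylation, cholesterol synthesis and ribosome biogenesis lists were lost (adjusted p = 0.0754, 0.0754 and 0.0936). Polr1b had the smallest p among its members (log2 fold change -0.29, SE 0.0895, adjusted p = 0.0602).

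Of 183 mTORC1-responsive genes, 1 was higher, 4 lower and 178 not called (median -0.08, camera adjusted p = 0.304). Adjusted over the list alone 1 was higher and 3 lower, and the list did not pass. Its median was -0.01 under quantile normalization and -0.02 with the authors' factor divided out. The median of all genes tested was -0.054 in the main fit. Mean scores of this list were 6.14 ± 0.01 in P95H and 6.22 ± 0.05 in Mx1-Cre (SD, n = 5). The exact permutation p was 0.00794 (0.127 after adjustment). Pfkl, a phosphofructokinase gene (-0.31, SE 0.0582), and Mthfd2l (-0.33, SE 0.0732) fell. Of 23 glycolysis genes, 0 were higher, 3 lower and 20 not called (0 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.342). The lower genes were Pfkl, Pklr, the red cell pyruvate kinase gene (-0.22, SE 0.0474), and Pfkm (-0.17, SE 0.0508). Pklr lost its call under quantile normalization and with the authors' factor divided out (adjusted p up to 0.124), and Pfkm under both (adjusted p = 0.199 and 0.358), in a fit of the compared groups alone, with no filter and without any 1 of Mx1-Cre PHZ replicates 1, 3, 4 and 5 or P95H PHZ replicates 2, 3 and 4 (adjusted p = 0.0785 to 0.113).

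Of 22 interferon-stimulated genes, 0 were higher, 0 lower and 22 not called (0 higher and 0 lower adjusted over the list alone, median 0.13, camera adjusted p = 0.00117). Members include Rsad2 at 0.49 (SE 0.161, adjusted p = 0.0729). The median was 0.21 without P95H PHZ replicate 2, and the call was lost under quantile normalization (adjusted p = 0.0952). Of 40 SR proteins and splicing factors, 1 was higher, 2 lower and 37 not called (1 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.185). Srsf2 itself and Clk3, a kinase that phosphorylates SR proteins (-0.34, SE 0.0676), were lower, and Hnrnpa2b1, which encodes an RNA-binding protein (0.23, SE 0.0566), was higher, a call lost without any 1 of Mx1-Cre PHZ replicates 1 and 3 or P95H PHZ replicates 3 and 5 (adjusted p = 0.0503 to 0.0586). Gp9 was higher by 0.54 (SE 0.149, adjusted p = 0.0399) but lost its call without any 1 of Mx1-Cre PHZ replicates 2, 3 and 5 or P95H PHZ replicates 1, 3 and 5 (adjusted p = 0.0648 to 0.106) and under quantile normalization, in a fit of the compared groups alone and with no filter, in a list of 6 megakaryocyte markers that did not pass (camera adjusted p = 0.0587). Granulocyte and monocyte markers were similar in level, at 2.72 ± 0.49 in P95H and 2.67 ± 0.82 in Mx1-Cre (SD, n = 5; exact permutation p = 0.881), with 0 higher and 0 lower of 18 (also 0 and 0 adjusted over the list alone). Il4, the 1 basophil and mast cell marker measured, was higher in P95H but missed the threshold (0.60, SE 0.194, adjusted p = 0.0706; exact permutation p = 0.0159, 0.17 after adjustment over the lists), and passed it with the granulocyte covariate and without P95H PBS replicates 4 and 5, or without P95H PBS replicate 5, P95H PHZ replicate 1 or Mx1-Cre PBS replicate 5 alone (adjusted p = 0.0346 to 0.0491).

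The interaction asks whether the PHZ response differed between genotypes. limma called 0 genes, with 577 at an unadjusted p under 0.05 and a smallest adjusted p of 0.798. The count was also 0 under TMM factors, quantile normalization, the factor divided out, library weights and every other setting run except 1. With no filter on low values it was 1, Cpne9, chosen after its values were seen (-0.96, SE 0.139, adjusted p = 0.0276), which is listed at 0 in all P95H PHZ libraries and averaged under 1 elsewhere. The genes with the smallest p were B3galt6, a galactosyltransferase gene (log2 fold change -0.43, SE 0.104), Cd59b (log2 fold change 0.56, SE 0.141), the small GTPase gene Rab21 (log2 fold change -0.31, SE 0.0804), Sac3d1 (log2 fold change -0.37, SE 0.0977) and Nxt2, an RNA export factor gene (log2 fold change 0.53, SE 0.145). Cd59b went from 7.43 ± 0.612 to 3.97 ± 0.664 in Mx1-Cre and from 7.82 ± 1.14 to 6.62 ± 0.769 in P95H. Srsf2 (log2 fold change -0.10, SE 0.0774, adjusted p = 0.798) and Fyn (log2 fold change -0.05, SE 0.135, adjusted p = 0.937) were not called.

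As lists, several PHZ responses were lower in P95H than in Mx1-Cre, although no member was called, either over all genes or adjusted over the list alone. The median difference was -0.12 for mTORC1-responsive genes (camera adjusted p = 5.4e-06), with Nampt of NAD synthesis at -0.27 (SE 0.0924) and the transcription factor gene Bhlhe40 at -0.44 (SE 0.181). The list median was -0.07 without Mx1-Cre PBS replicate 4, -0.06 under quantile normalization and -0.06 with the authors' factor divided out. Ribosome biogenesis had a median difference of -0.16 (camera adjusted p = 6.29e-08), which was -0.10 without P95H PHZ replicate 5, -0.09 under quantile normalization and -0.10 with the authors' factor divided out. Oxidative phosphorylation had one of -0.12 (camera adjusted p = 2.65e-10), with Ndufs4 at -0.21 (SE 0.0784). It was -0.04 under quantile normalization and -0.07 with the authors' factor divided out. Cytosolic ribosomal proteins were at -0.12 (camera adjusted p = 2.63e-06), and at -0.08 without Mx1-Cre PHZ replicate 5. With the authors' factor divided out or the granulocyte covariate they were at -0.07. Quantile normalization ended the call (-0.03, adjusted p = 0.0728). Granulocyte and monocyte markers also fell more (-0.89, camera adjusted p = 0.000104). Their difference was -0.46 without Mx1-Cre PHZ replicate 5 and lost its call without P95H PBS replicates 4 and 5 (adjusted p = 0.338).

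**Figure D2:**
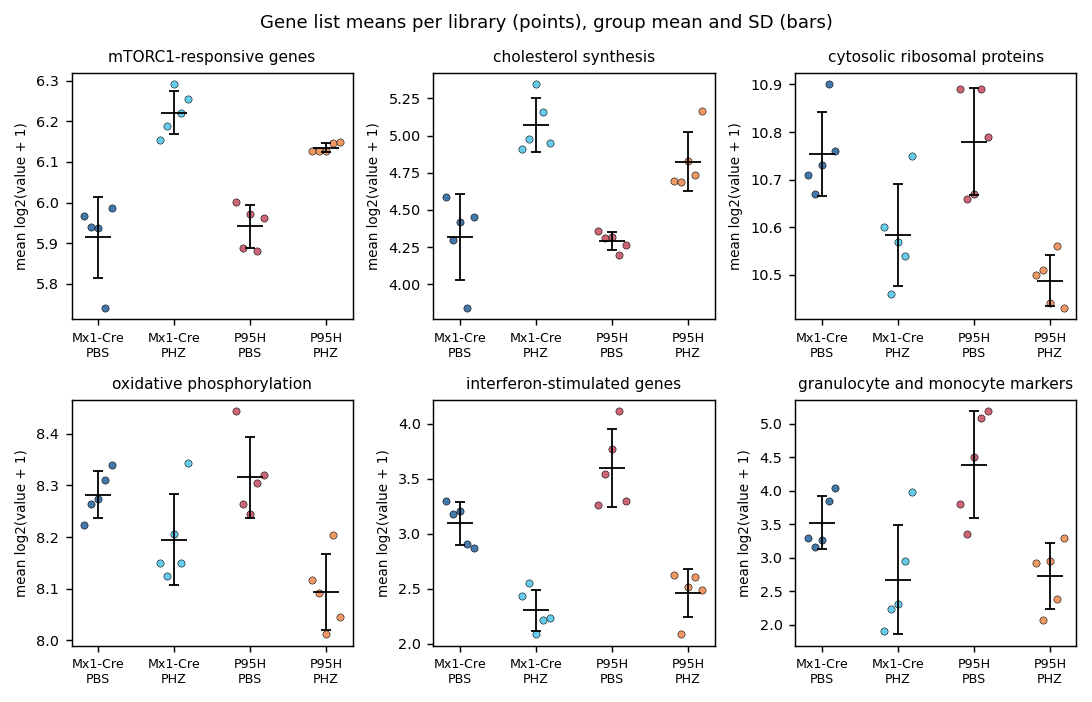
Mean log2(value + 1) of 6 gene lists per library (vertical axes do not start at 0), for Mx1-Cre and P95H mice after PBS or PHZ. Points are libraries and bars the group mean and SD of 5; the mTORC1-responsive mean is 5.91 and 6.22 in Mx1-Cre PBS and PHZ, and 5.94 and 6.14 in P95H, while granulocyte markers are highest in P95H PBS at 4.39.

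Across genes, the PHZ effects of the genotypes correlated (Pearson r = 0.871, Spearman rho = 0.788 over 10890 genes, which are not independent replicates). In both genotypes 1056 genes were higher (234 if the calls were independent) and 1148 lower (286), and 0 were called in opposite directions. The P95H effects under PBS and PHZ correlated less (Pearson r = 0.437, Spearman rho = 0.381), with 13 genes higher in both (0.43 if independent), 71 lower in both (5.33) and 0 opposite. Each pair of contrasts shares no library.

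**Figure D3:**
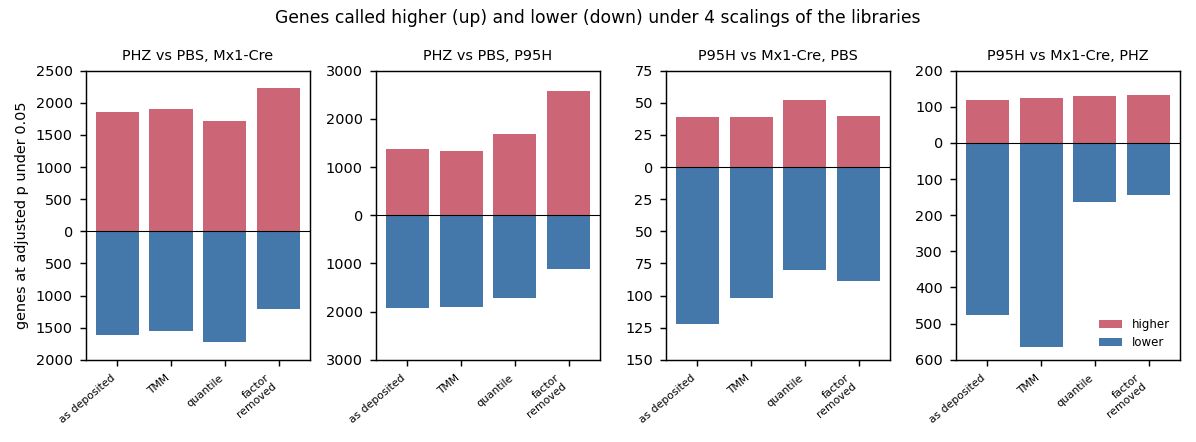
Genes at an adjusted p under 0.05 that were higher (bars up) or lower (bars down) in 4 comparisons, with the values as deposited and under 3 other scalings. For P95H against Mx1-Cre after PHZ, lower calls number 476 as deposited, 565 under TMM, 163 under quantile normalization and 145 with the authors' factor divided out.

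Of the genes that lead these comparisons, Podxl is ENSMUSG00000025608, chromosome 6, 31519488 to 31563981, minus strand, Fabp5 is ENSMUSG00000027533, chromosome 3, 10012548 to 10016607, plus strand, Smo is ENSMUSG00000001761, chromosome 6, 29735503 to 29761365, plus strand, Rbks is ENSMUSG00000029136, chromosome 5, 31624439 to 31697627, minus strand, Ndufb8 is ENSMUSG00000025204, chromosome 19, 44548572 to 44555440, minus strand and Rtp4 is ENSMUSG00000033355, chromosome 16, 23520291 to 23614222, plus strand. All are protein-coding, and the positions are whole gene spans on GRCm38.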

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

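The tests of a granulocyte-marker covariate on the interferon-stimulated list, of a lymphoid-marker covariate and of GC content and transcript length on the surplus of lower calls were chosen after the results were seen. Among 299 gene and group sets, 128 list and group sets and 24 library measures, 14, 10 and 2 had a library set apart from the other 4 by more than 0.71 of the group's range, where chance gives about 1 in 20 groups (5%). Mx1-Cre PBS replicate 4 was the library apart in many of them. It was lowest for Fabp5 (gap over range 0.741), Mthfd2 (0.788), Psat1 (0.76), Calr (0.771) and Akt1 (0.764), and for the list means of the ATF4 and amino acid response (0.781), mTORC1-responsive genes (0.797) and NRF2 targets (0.776). It was highest for the HIF target mean (0.758), the authors' factor (0.726) and the share of the 10 most abundant entries (0.714). Other libraries stood apart for Ctsc in Mx1-Cre PBS (0.925, lowest replicate 3) and, in Mx1-Cre PHZ, for Amigo2 (0.847, lowest replicate 4), Ms4a3 (0.727, highest replicate 5) and Uqcrh (0.772, highest replicate 5). In P95H PBS they were Tfrc (0.786, lowest replicate 4), Pfkp (0.787, lowest replicate 2), Smo (0.718, highest replicate 3), the basophil and mast cell mean (0.734, lowest replicate 5) and the lymphoid mean (0.829, highest replicate 3). In P95H PHZ they were Hmmr (0.755, lowest replicate 4), Rsad2 (0.718, lowest replicate 2), and the means of the BCL2 family (0.805, highest replicate 5), interferon-stimulated genes (0.747, lowest replicate 2), iron handling (0.736, highest replicate 1) and NF-kB and inflammatory genes (0.765, lowest replicate 1).

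The PHZ effects of the genotypes differed for 13 lists by camera with its preset correlation, and for none of them with an estimated correlation (adjusted p at least 0.639). The median differences, P95H minus Mx1-Cre, were -0.116 for mTORC1-responsive genes, -0.158 for ribosome biogenesis, -0.124 for oxidative phosphorylation, -0.124 for cytosolic ribosomal proteins, -0.885 for granulocyte and monocyte markers and -0.112 for NRF2 targets. Quantile normalization gave -0.0558, -0.0855, -0.044 and -0.0295 for the first 4 of these, and the authors' factor divided out gave -0.0584, -0.0997, -0.0652 and -0.0651. The first was -0.0668 without Mx1-Cre PBS replicate 4, ribosome biogenesis -0.102 without P95H PHZ replicate 5, and ribosomal proteins -0.0784 and granulocyte markers -0.456 without Mx1-Cre PHZ replicate 5. NRF2 targets were at -0.0665 without Mx1-Cre PBS replicate 4 and lost their call under quantile normalization (adjusted p = 0.0669), with the granulocyte-marker covariate (0.0821) and without P95H PBS replicates 4 and 5 (0.0598). Interferon-stimulated genes were at -0.293, a call lost without any 1 of P95H PBS replicate 4 or P95H PHZ replicate 2 (adjusted p = 0.0506 to 0.105), and cholesterol synthesis at -0.201, lost without any 1 of Mx1-Cre PBS replicate 4 or Mx1-Cre PHZ replicate 3 (adjusted p = 0.0574 to 0.226). The amino acid response was at -0.123, lost without any 1 of Mx1-Cre PBS replicate 4, Mx1-Cre PHZ replicate 3 or P95H PBS replicates 1 and 3 (adjusted p = 0.0512 to 0.254), and the unfolded protein response at -0.139, lost without any 1 of Mx1-Cre PBS replicate 4, Mx1-Cre PHZ replicate 2 or P95H PHZ replicate 5 (adjusted p = 0.0925 to 0.0997). Library weights ended the calls of interferon-stimulated genes and of the amino acid response (adjusted p = 0.194 and 0.159), and the unfolded protein response was at -0.0808 under quantile normalization and -0.0812 with the factor divided out. Mitosis genes were at 0.0468, lost without any 1 of Mx1-Cre PBS replicate 3 or P95H PHZ replicate 1 (adjusted p = 0.0561 to 0.0701) and without P95H PBS replicates 4 and 5 (adjusted p = 0.0598). Their median was 0.0922 without Mx1-Cre PBS replicate 4, 0.0721 without Mx1-Cre PHZ replicate 1, 0.0261 without Mx1-Cre PHZ replicate 2 and 0.0781 without P95H PHZ replicate 2. Erythroid maturation was at 0.0642, lost without any 1 of Mx1-Cre PBS replicate 3, Mx1-Cre PHZ replicate 5 or P95H PHZ replicates 1 and 5 (adjusted p = 0.0809 to 0.394), the last of which turned it to -0.0199. It was also lost with no filter (adjusted p = 0.101) and without P95H PBS replicates 4 and 5 (adjusted p = 0.0677). Its median was 0.111 without Mx1-Cre PBS replicate 5 or Mx1-Cre PHZ replicate 1, 0.145 without P95H PHZ replicate 2 and 0.121 without P95H PHZ replicate 4. Globins, whose near-identical copies make single values uncertain, were at 0.339, lost without any 1 of Mx1-Cre PBS replicates 2, 3 and 4, Mx1-Cre PHZ replicates 2, 3 and 5, P95H PBS replicates 3, 4 and 5 or P95H PHZ replicates 1 and 5 (adjusted p = 0.053 to 0.242), and were at 0.522 without P95H PHZ replicate 4. The globin call was also lost with no filter, the filter at 5, the granulocyte-marker covariate and without P95H PBS replicates 4 and 5 (adjusted p up to 0.349). Quantile normalization and the authors' factor divided out ended it too (adjusted p = 0.0649 and 0.12) and gave 0.129 and 0.105 for mitosis genes and 0.138 and 0.121 for erythroid maturation.

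Interferon-stimulated genes were higher in P95H PBS (median 0.459) and fell after PHZ in P95H (-1.16), moving with granulocyte and lymphoid markers. With the marker mean as a covariate the PBS difference kept 1.01 of its size (leave-one-out SE 0.225), which argues against granulocyte-lineage cells as the whole cause. Other scalings kept at least 0.998 (SE 0.032). The authors' factor averaged 1.027 in both groups, so removing it could change little. For the fall after PHZ, 0.92 (SE 0.0324) was kept under other scalings, and the covariate kept 0.942 (SE 0.242), within 2 SE of the 0.5 that would be needed, so that explanation stays open there. With the mean of the 3 lymphoid markers as a covariate 0.619 (SE 0.384) of the PBS difference and 0.552 (SE 0.391) of the fall were kept, both within 2 SE of 0.5, so lymphoid cells, the genotype and cells of types not tested may contribute.

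The mTORC1-responsive list rose less after PHZ in P95H (median difference -0.116). Under quantile normalization 0.479 of the difference was kept (SE 0.354), below the 0.5 named before the test as the mark of a scaling effect, but within 2 SE of it, and the rule that such a value leaves the question open was set after it was seen. The granulocyte-marker covariate kept 0.997 (SE 0.315) and the lymphoid-marker covariate 0.692 (SE 0.367), also within 2 SE of 0.5. Chance could not be excluded, since 5 of 100 splits gave a difference as large (real 0.116, highest other 0.14). Scaling, other cells, chance and the genotype thus remain possible.

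The surplus of lower calls in P95H after PHZ (79.9% of calls) dropped to 52.2% with the authors' factor divided out and to 55.8% under quantile normalization, and was 82.1% under TMM, so the authors' scaling may account for it. With each library's trend against GC content removed the share was 79.8% (lowest 78.6% with a library left out), and against transcript length 84.8% (lowest 81.7%). It was 82.4% for the same genes with no trend removed. This test kept each library's own level, on which the surplus depended, so it cannot decide on these trends. That test replaced an earlier version, after its outcome was seen, which also centred each library and gave 45.9% for GC content and 48.7% for length. Centring alone, with no trend removed, gave 56.4%, so the earlier version could not part a trend from a change of scaling. Features were known for 93.5% of the calls.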

How the results depend on the processing

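Depth is unknown, so it could not be weighed here. The choices added after the data were seen were the authors' factor divided out, the granulocyte-marker covariate and leaving out P95H PBS replicates 4 and 5. Scaling moved the median of all genes by less than 0.1. The cause of each change below was not tested, except that fewer libraries were used where libraries were left out. PHZ in P95H gave 992 calls with the covariate and 2089 without replicates 4 and 5. P95H under PBS gave 78 in a fit of the compared groups alone, 538 with library weights, 107 with the covariate and 97 without those replicates. P95H under PHZ gave 292 under quantile normalization, 345 in the compared groups alone and 278 with the factor divided out. The interaction gave 1 with no filter, where the mTORC1-responsive list under PHZ also passed (-0.071, adjusted p = 0.00238). Leaving out each library gave 2596 to 3489 for PHZ in Mx1-Cre, 2686 to 3437 for PHZ in P95H, 90 to 180 for P95H under PBS, 319 to 697 for P95H under PHZ and 0 to 0 for the interaction. The mTORC1-responsive medians then ran from 0.198 to 0.261, 0.132 to 0.171, -0.00964 to 0.0515, -0.0885 to -0.0638 and -0.133 to -0.0668 in that order, reversed for P95H under PBS without Mx1-Cre PBS replicate 4 (-0.00964). Also reversed were the EPO and STAT5 list for PHZ in P95H with the covariate (-0.024), the amino acid list for P95H under PBS without Mx1-Cre PBS replicate 4 (-0.0027) and erythroid maturation in the interaction without P95H PHZ replicate 5 (-0.0199). Ribosomal proteins for P95H under PBS reversed without Mx1-Cre PBS replicate 2 (-0.00341), without P95H PBS replicate 4 (-0.00883), with the covariate (-0.0329) and without P95H PBS replicates 4 and 5 (-0.0209). Among the larger values were the amino acid list for P95H under PBS without Mx1-Cre PBS replicate 5 (0.084), ribosomal proteins without Mx1-Cre PBS replicate 4 (0.0713) and erythroid maturation in the interaction without P95H PHZ replicate 2 (0.145). Of the values for named genes and for lists, 3928 and 3454 kept direction and side of the threshold. The covariate fixes the outcome of the granulocyte list and its genes, which were left out of it. Replicate numbers do not pair the libraries: those with the same number correlated at a median of 0.0521 (-0.244 to 0.399; 10 of 30 pairs over 0.1), and 5 of 20 were closest to their own number. The replicate block gave 3579, 3356, 189, 617 and 0 calls.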

Other observations

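The tests of exon number, of GGNG and CCNG motifs and of mitochondrial ribosomal proteins were written down before their results were seen, and the genes of the next 2 paragraphs and the sum of the P95H effects were chosen after theirs.

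Of the 71 genes that were lower in P95H under both treatments, Ccnd1, which encodes cyclin D1, had the largest mean change, with -1.63 under PBS (adjusted p = 0.000188) and -0.82 after PHZ (adjusted p = 0.0214, limma). Nup210, a nuclear pore gene, was at -0.49 and -0.52, the base excision repair gene Nthl1 at -0.54 and -0.68, Aldh7a1, an aldehyde dehydrogenase gene, at -0.39 and -0.54, and the transcription factor gene Tfcp2 at -0.57 and -0.55. The purine synthesis regulator gene Prpsap2 was at -0.61 and -0.43. Among the 13 genes higher in both were Dpp7 (0.57 and 0.53) and Idua (0.49 and 0.52), which encode lysosomal enzymes, Lyplal1 (0.74 and 0.52) and Sat1 of polyamine breakdown (0.30 and 0.27).

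Genes for the proteins used in the sort also moved. Kit, for which high cells were gated, fell after PHZ by 0.80 in Mx1-Cre (SE 0.155, adjusted p = 0.00073) and by 0.77 in P95H (SE 0.155, adjusted p = 0.000962), and Eng, which encodes CD105, by 0.19 (SE 0.0629, adjusted p = 0.028) and 0.17 (SE 0.0629, adjusted p = 0.043). Kit averaged 108 ± 27.5 in Mx1-Cre PBS and 60.6 ± 5.72 in Mx1-Cre PHZ (SD, n = 5). Of the genes for excluded proteins, Ly6a (Sca-1) and Slamf1 (CD150) averaged under 1 in every group, with highest means of 0.737 and 0.107. Itga2b (CD41) averaged up to 1.66 ± 0.353 in Mx1-Cre PBS, and Fcgr3 (CD16) and Fcgr2b (CD32) up to 1.96 ± 1.14 and 1.3 ± 0.637 in P95H PBS. Itga2b fell after PHZ by 0.55 in Mx1-Cre (SE 0.116, adjusted p = 0.00128), and Fcgr3 by 0.62 in P95H (SE 0.233, adjusted p = 0.0489). In P95H the change of Itga2b missed the threshold (-0.28, adjusted p = 0.0679), as did that of Fcgr3 in Mx1-Cre (-0.36, adjusted p = 0.251).

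A hypothesis was that genes lower in P95H under both treatments hold more exons. Their median exon number was 12 against 9 in 10000 expression-matched random sets (percentile 99, 68 of 71 genes with features). Length was not matched nor splicing tested, so no link is claimed. Another hypothesis was that their transcripts hold more GGNG than CCNG motifs, between which the mutation is reported to shift the protein's preference. The median log2 ratio of CCNG to GGNG was 0.0715 against 0.14 in random sets, percentile 12, which does not set the genes apart. A further hypothesis was that nuclear transcripts for mitochondrial proteins in general were lower in P95H after PHZ. The 78 mitochondrial ribosomal protein genes had a median of -0.0714 against -0.0679 in random sets (percentile 40.2), with 2 called lower, so these genes did not stand apart from others of like expression. Whether the oxidative phosphorylation genes share a shift with genes for mitochondrial proteins other than these was not tested.

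Among 100 splits of the libraries, chance could be excluded for the counts of PHZ in Mx1-Cre (1 split as large, the real one; 3474 against 468 at most in another), PHZ in P95H (1; 3294 against 850), P95H under PBS (1; 161 against 13) and P95H under PHZ (1; 596 against 8). For the interaction the test says nothing on chance, because the real count of 0 is reached by every one of the 100 splits. The highest other gave 114, in a split where 0 of 5 P95H PBS and 4 of 5 P95H PHZ libraries kept their label. This exchanges the P95H PBS and Mx1-Cre PBS labels, so the split compares about the sum of the 2 P95H effects. For that sum limma called 1148 genes, which held 112 of the 114 in the same direction, so the P95H effects may be the structure of the samples that this split points to. For the mTORC1-responsive median, chance could be excluded for PHZ in Mx1-Cre (1 split as large; 0.236 against 0.201) and PHZ in P95H (1; 0.16 against 0.13), but not for P95H under PBS (64; 0.0296 against 0.0926). For P95H under PHZ 3 splits gave a median as large in size, with 0.0757 for the real one and 0.0831 for the highest other. The list did not pass camera there (adjusted p = 0.304), so no change of the list is claimed.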
